A study of Cyanidioschyzon merolae with 30 samples.

How the data were processed

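RNA was sequenced from 30 cultures of the unicellular red alga *Cyanidioschyzon merolae*, 15 of the wild-type strain 10D (WT) and 15 of the Polycomb mutant Cme(z)-1 (EZ). The mutant carries a disrupted E(z) gene, whose product is the catalytic subunit of the Polycomb complex that methylates histone H3 at lysine 27. Cultures grew at 42 °C and were sampled in 5 states, with 3 libraries per genotype and state. NL cultures were left untreated until the end of a 24 h lag. P cultures were sampled after 30 min at 57 °C. PL cultures had the same 30 min at 57 °C followed by the 24 h lag at 42 °C. T cultures had the lag and then 15 min at 60 °C with no earlier heat, and PLT cultures had the 57 °C treatment, the lag and the 60 °C treatment. The series text describes the replicates as biological. Untreated cultures of the time of P belong to another series and were not used here, so NL, harvested about 24 h later, served as the control of P. The 6 columns of the deposited table that hold those samples were left out.

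The values are gene counts deposited by the authors in 1 table, not normalised. Libraries were made from polyadenylated RNA with an unstranded NEBNext kit and sequenced on a NovaSeq instrument, per the labels' protocols. STAR 2.7.9a and featureCounts 2.0.1 are named in the submitters' processing notes. The genome build, the annotation, the strand setting and the handling of reads with several matches are not given in the sources used here. Reads from a gene and an overlapping neighbour on the other strand therefore cannot be told apart, and counts of near-identical copies are uncertain.

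The table lists 5009 gene identifiers, of which 50 had no count in any library used. Total counts ranged from 6276214 to 15336903 per library, with a mean of 8558566 ± 2177851 (SD, n = 30). At this depth, a gene with 0 counts in a library has an upper limit of 3 counts, which is 0.199 to 0.478 counts-per-million units (CPM) in the EZ libraries. Intervals on shares of counts are exact Clopper-Pearson 95% intervals. Intervals and upper limits cover counting error only. Pairs of libraries within a group differed by more than sampling noise, with chi-square per degree of freedom between 16.3 and 908 over genes with at least 20 counts per pair, so no library was taken for a copy of another.

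Samples were grouped by their titles. Both PL libraries numbered 2 have a library name that gives the other genotype than the title and the genotype label, and the treatment label of EZ P replicate 1 names the wild type. Counts of the E(z) gene (CMQ156C) went with the titles in all 30 libraries. Exchanging the genotypes of both PL libraries numbered 2, and leaving both out, were run as alternatives.

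Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust fitting) on the counts as deposited. Libraries were scaled by TMM factors, genes were filtered by filterByExpr, and each of the 10 groups had its own mean in 1 model over all 30 libraries. Of the identifiers, 4878 passed the filter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 CPM use a prior count of 2, and log2 fold changes are those of the edgeR fit. A gene's CPM are on the TMM-scaled library sizes unless raw totals are named. The comparisons were P, T and PL against NL, PLT against T, EZ against WT in NL, the EZ minus WT difference of each heat comparison, and the PLT minus T difference against the PL minus NL difference within each genotype. The scripts were tested on simulated data before use. In counts simulated for WT PL against NL, with 50 of 4876 genes changed per fold size, the fit recovered 46% of genes changed 1.5-fold, 84% of those changed 2-fold, 98% at 4-fold and 96% at 8-fold, and called 5 unchanged genes. A fit on only the libraries of both groups (4789 genes) recovered 30%, 80%, 96% and 100% and called 14 unchanged genes.

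Gene sets were tested with limma 3.58.1 (camera, two-sided, preset correlation between genes of 0.01), adjusted over the 3 sets of a comparison, and again with an estimated correlation. The identifiers were matched to a RefSeq gene table of assembly ASM9120v1. It held 4756 of the 5009 identifiers, all protein coding, with no names other than locus tags. The functional lists planned before the data were examined needed product names and could not be formed. A planned list of genes within 20 kb of a chromosome end was replaced, since the build of the counts is not named, by the 5 outermost protein-coding genes at each end of the 20 nuclear chromosomes (200 genes, 191 tested), taken from gene order alone. That definition, its alternatives of 3 and 10 genes, and the sets of plastid genes (196 of 207 tested) and mitochondrial genes (3 of 34 tested), taken by identifier, were chosen after the data were seen. No coordinates are printed.

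Genes are named by a rule written before the data were examined. It takes the E(z) gene, the small heat shock protein genes CMJ100C and CMJ101C, the 2 largest rises and the 2 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between groups, and up to 4 members with the smallest adjusted p in each set called (up to 2 in the EZ heat comparisons). A part of the rule on genes with product names selected nothing. CMJ099C, CMJ103C, CME030C, CMI250C, CMJ308C and the end genes not taken by the rule were chosen after their values were seen, as was CMJ102C in WT PLT against T and CMT010C in comparisons other than that.

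Replicate numbers recur in every group. The deviations of same-numbered libraries from their group means correlated across genes in every pair for WT PLT and T (r from 0.483 to 0.660), EZ PLT and T (0.172 to 0.374), and EZ and WT in NL (0.224 to 0.559), and not in every pair of any other comparison. For those 3 comparisons the numbers were taken to pair the libraries, from these correlations and not from a label, and a fit with the replicate number as a block is given beside a count where it moved it by more than 1.5 times.

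The alternatives were scaling by RLE, no filter on low counts, a minimum mean log2 CPM of 3, a minimum absolute log2 fold change of 1, DESeq2 1.42.0, a fit on only the groups compared, the replicate block, organelle genes left out, the PL settings above, and leaving out each library in turn. A fit without the 6 P libraries, the left-out WT P replicate 2 in comparisons that do not use WT P, and the genotype effect averaged over the 5 states were added after the data were seen. Response scores are the mean log2 CPM, per library, of nuclear genes called with at least a 2-fold change in P of the other genotype, CMJ101C left out. The higher list held 402 genes for WT libraries and 485 for EZ libraries, and the lower list 147 and 175. Score levels are therefore not comparable between genotypes. Scores were compared by exact two-sided permutation within genotypes (400 arrangements), adjusted over 4 tests. For PLT against T they were also compared by exchanging labels only within the pairs of same-numbered libraries (64 arrangements), adjusted over those 2 tests. Both were added after the data were seen, as were the alternatives for the plastid set of differences between effects. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.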

Results

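Transcripts of *C. merolae*, a red alga of acidic hot springs, were counted in 30 libraries to follow how an earlier heat treatment bears on the response to a later one, and whether the Polycomb gene E(z) takes part. Each of the 10 groups, made by 2 genotypes and 5 states, had 3 libraries. Total counts per library averaged 8558566 ± 2177851 (SD, n = 30) and ranged from 6276214 to 15336903.

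The disrupted gene was examined first. E(z) (CMQ156C), the histone methyltransferase of the Polycomb complex, stood at 185.0 ± 10.2 CPM (counts-per-million, here of the raw totals) in WT NL libraries (SD, n = 3). It had 0 counts in all 15 EZ libraries, which allows at most 0.199 to 0.478 CPM per library. With the 3-count floor applied to each EZ NL library, its level was at least 506-fold lower in EZ than in WT. In WT P it stood at 73.5 ± 43.2 CPM of raw totals, while on TMM-scaled libraries the log2 fold change against NL was -0.33 (adjusted p = 0.0121).

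Heat state accounted for most of the variation between libraries. The first principal component held 55.7% of the variance and was highest in 5 of the 6 P libraries, and the second (13.7%) separated T and PLT from NL and PL. The third (10.2%) was above 0 in every WT library and below 0 in every EZ library. WT P replicate 2 lay at 12.6 on the first component, below WT PLT replicate 1 (at 16), while WT P replicates 1 and 3 lay at 61.6 and 72.0 and the EZ P libraries at 35.9, 26.7 and 62.8.

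**Figure D1:**
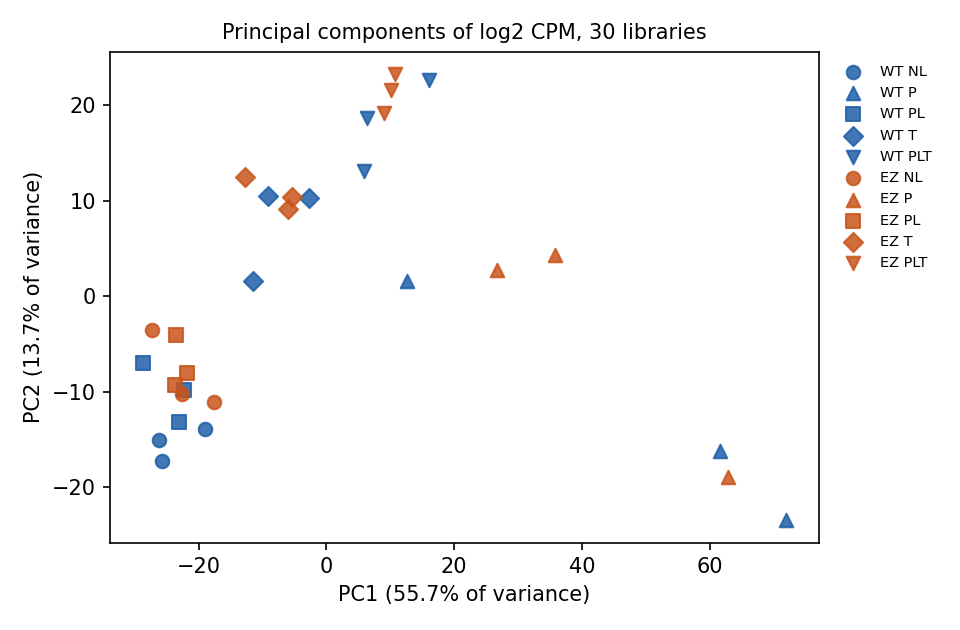
Principal components 1 and 2 of log2 CPM for the 30 libraries, with 1 point per library, colour for genotype and marker for state. P libraries spread from 12.6 to 72.0 along component 1, where 1 PLT library stands at 16, and NL and PL libraries of both genotypes lie together at the left.

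The direct effect of 30 min at 57 °C in wild type was measured by comparing P with NL. CMJ101C, which encodes a small heat shock protein, a chaperone that binds unfolding proteins, rose the most among the genes eligible for naming. Its share of all counts went from 0.00231 ± 0.000637% in NL to 13.3 ± 9.13% in P (SD, n = 3 each). The P libraries held 17.8%, 2.84% and 19.4%, each with an exact Clopper-Pearson 95% interval narrower than the differences between them (2.83% to 2.85% for replicate 2). The log2 fold change was 13.96 ± 1.07 (SE, adjusted p = 1.82e-09). CMC125C followed at 10.09 ± 0.87, from 64.3 ± 9.61 to 69858 ± 54250 CPM. The largest falls among eligible genes were in CMG220C, from 209.8 ± 45.6 to 35.7 ± 21.8 CPM (log2 fold change -2.50 ± 0.26), and CMK108C, from 61.8 ± 11.9 to 12.3 ± 4.90 CPM (-2.24 ± 0.24). CMJ100C, the other small heat shock protein gene fixed for naming, had 0 counts in every library. Whether reads common to both copies were dropped or given to CMJ101C is not known from the table.

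**Figure D2:**
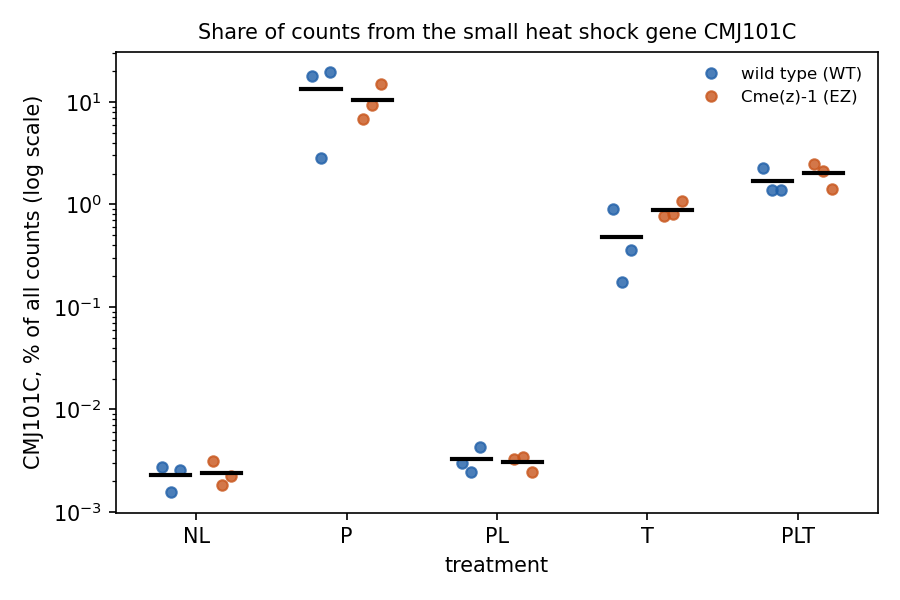
Share of all counts from CMJ101C per library, on a log axis, by state and genotype, with bars at the mean of 3 libraries. The mean share is 0.00231% in WT NL, 13.3% in WT P, 0.479% in WT T and 1.69% in WT PLT.

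In all, 2618 of 4878 genes tested were called in WT P against NL, 1324 higher and 1294 lower. Of these, 815 changed at least 2-fold, 636 higher and 179 lower. Among 196 plastid genes, 160 were higher, 3 were lower and 33 were not called, with a median log2 fold change of 2.70. CMV077C rose by 7.52, CMV076C by 7.16, CMV047C by 6.88 and CMV121C by 6.56 on the log2 scale. CMV077C, CMV076C and CMV121C were near the floor in NL, at 0.334 ± 0.326, 0.485 ± 0.423 and 0.330 ± 0.211 CPM. The size of their rise is therefore uncertain, while CMV047C started from 10.1 ± 2.82 CPM. The plastid set was called by camera with the preset correlation (adjusted p = 5.32e-18) and not with an estimated one (adjusted p = 0.518). Plastid genes held 0.752 ± 0.068% of raw counts in NL and 0.865 ± 0.249% in P, a difference within the spread between P libraries. The 3 mitochondrial genes tested held 1 higher, 1 lower and 1 not called, and the set was not called (adjusted p = 0.620). Of 191 genes at chromosome ends, 44 were higher and 53 lower, and this set was not called either (adjusted p = 0.620). Among end genes, CMO355C rose by 1.55 and CMT009C by 1.27, and CMK308C stood at -1.91. The 10 most abundant genes held 30.3 ± 14.9% of counts in P against 7.42 ± 0.0796% in NL, and the TMM factors of the P libraries were 0.435, 0.871 and 0.380. A fit on only the P and NL libraries called 1462 genes, 765 higher and 697 lower. NL was harvested about 24 h after P, so a change with time in culture would count as a change in P.

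The 60 °C treatment without earlier heat was assessed in wild type by comparing T with NL. CMJ101C again rose the most, to 0.479 ± 0.374% of counts (SD, n = 3; log2 fold change 7.75 ± 0.85, adjusted p = 9.25e-07). CMC125C went from 64.3 ± 9.61 to 1148 ± 587.9 CPM (4.16 ± 0.67). The largest falls among eligible genes were in CMV141C (-1.46 ± 0.46) and CMT050C (-1.42 ± 0.40). Of 1062 genes called, 558 were higher and 504 lower, and 73 changed at least 2-fold, 50 higher and 23 lower. Among plastid genes, 18 were higher, 3 lower and 175 not called, with a median of 0.28. CMV077C rose by 4.79, CMV076C by 4.51, CMV079C by 3.16 and CMV071C by 2.97. In NL, CMV077C, CMV076C and CMV079C (0.558 ± 0.356 CPM) were near the floor, while CMV071C stood at 14.1 ± 4.82 CPM. The plastid set was called with the preset correlation (adjusted p = 0.0303) and not with an estimated one (adjusted p = 0.707). Its median was -0.039 without WT T replicate 1, and the call was lost without WT NL replicate 1 (median 0.17, adjusted p = 0.253) or WT NL replicate 2 (0.26, adjusted p = 0.0517). At chromosome ends 28 genes were higher and 14 lower, and the set was not called (adjusted p = 0.744), nor was the mitochondrial one (adjusted p = 0.447). CMO355C, an end gene, rose by 1.21. The count of called genes fell to 608 without WT T replicate 3 and to 693 without WT NL replicate 1, and was 1634 (816 higher, 818 lower) with the 6 P libraries left out of the fit.

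Whether the 57 °C treatment left a difference 24 h later was asked by comparing PL with NL. In wild type CMJ101C was back to 0.00325 ± 0.000953% of counts in PL, against 0.00231 ± 0.000637% in NL, with a log2 fold change of 0.44 ± 0.65 (adjusted p = 0.937). E(z) stood at -0.017 ± 0.098. edgeR called 0 genes in WT PL against NL, with 354 at an unadjusted p under 0.05, and DESeq2 called 3. The smallest adjusted p (0.219) belonged to CMT010C, the fourth protein-coding gene from a chromosome end. Its level was 15.9 ± 5.96 CPM in NL and 6.58 ± 0.710 CPM in PL (log2 fold change -1.27 ± 0.26). The plastid set had a median of -0.12 and was not called (adjusted p = 0.182, and 0.760 with an estimated correlation). It was called lower without WT NL replicate 1 (-0.22, adjusted p = 0.000447), WT PL replicate 2 (-0.23, adjusted p = 0.0150) or WT PL replicate 3 (-0.19, adjusted p = 0.00437), each at the preset correlation, and its median was above 0 without WT NL replicate 3 (0.067) or WT PL replicate 1 (0.046). The mitochondrial and chromosome-end sets were not called (adjusted p = 0.396 and 0.603). Without WT NL replicate 2, edgeR called 2 genes. In the simulation of this comparison, with 50 genes changed per fold size, the fit recovered 84% of those changed 2-fold and 46% of those changed 1.5-fold. The simulation changed genes of all fold sizes together, which makes the adjusted threshold easier to pass than with few changed genes. Differences between PL and NL could therefore go uncalled, and not only those under 2-fold. CMT010C, at -1.27, was not called.

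The effect of the 57 °C treatment on the later response was measured by comparing PLT with T. In wild type, 25 genes were called, 23 higher and 2 lower. Of the higher genes, 21 were plastid genes, and the others were CMJ102C and CME030C. CMV025C rose by 4.40 ± 0.77, CMV004C by 4.21 ± 0.79, CMV047C by 3.50 ± 0.64, CMV010C by 3.32 ± 0.64 and CMV082C by 2.56 ± 0.47 on the log2 scale (adjusted p = 0.0147 for CMV025C and 0.0150 for the others). CMV025C and CMV004C were near the floor in T, at 0.347 ± 0.230 and 0.823 ± 0.302 CPM, so the size of their rise is uncertain. CMV047C, CMV010C and CMV082C stood at 38.8 ± 28.9, 13.3 ± 8.62 and 16.6 ± 8.44 CPM in T. The median over the plastid set was 1.57, 21 genes were higher and 0 lower over all genes tested, and 110 were higher adjusted over the list alone. Camera called the set with the preset correlation (adjusted p = 1.33e-74) and with an estimated one (adjusted p = 0.0184). As a share of raw counts, plastid genes held 0.730 ± 0.224% in T and 1.22 ± 0.446% in PLT. CMJ102C, which neighbours CMJ101C, was at 65.5 ± 24.6 CPM in T and 609.8 ± 275.0 CPM in PLT (3.22 ± 0.44, adjusted p = 0.000632), with 46.6 ± 1.15 CPM in NL. CMJ101C itself held 0.479 ± 0.374% of counts in T and 1.69 ± 0.514% in PLT, and was not called (1.89 ± 0.65, adjusted p = 0.298). The genes lower in PLT were CMT010C, at 17 ± 4.1 CPM in T and 6.61 ± 0.306 CPM in PLT (-1.36 ± 0.27, adjusted p = 0.0150), and CMR288C (-0.50 ± 0.11, adjusted p = 0.0311). With organelle genes left out, 1 gene was called higher and 0 lower, so neither of these calls held. The chromosome-end and mitochondrial sets were not called (adjusted p = 0.205 and 0.136), but the former was called lower without WT T replicate 2 (median -0.036, adjusted p = 0.0433 at the preset correlation, and 0.153 over all libraries with an estimated one). The count rested on single libraries, being 1 without WT T replicate 2, WT T replicate 3 or WT PLT replicate 1, 16 without WT T replicate 1, 42 without WT PLT replicate 2 and 88 without WT P replicate 2. It was 52 (48 higher, 4 lower) with the replicate number as a block, 115 with the P libraries left out, 82 by DESeq2 and 0 in a fit on only the T and PLT libraries, where 578 genes had an unadjusted p under 0.05.

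**Figure D3:**
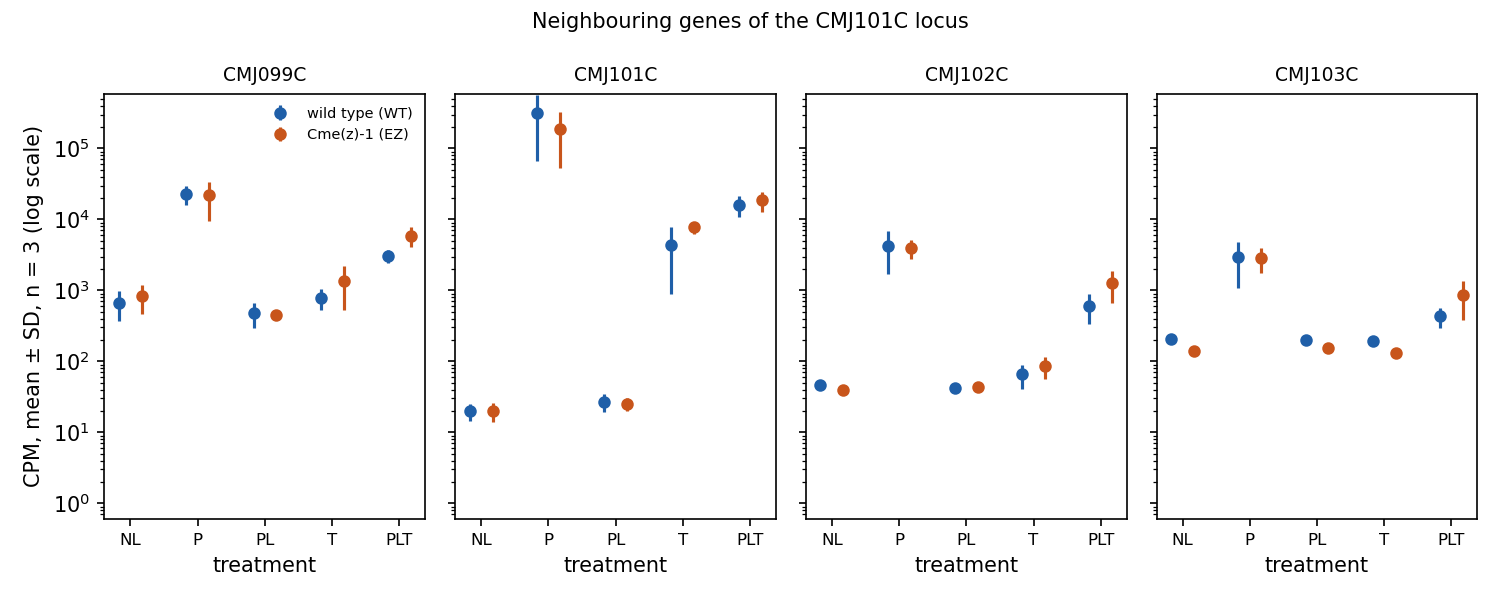
CPM (log axis) of CMJ101C and its neighbours CMJ099C, CMJ102C and CMJ103C by state, as means ± SD of 3 libraries per genotype. In WT, CMJ102C stands at 46.6 CPM in NL, 65.5 in T and 609.8 in PLT.

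The same comparisons were made in the mutant. In EZ P against NL, CMJ101C rose to 10.4 ± 4.23% of counts (SD, n = 3; log2 fold change 13.19 ± 1.04, adjusted p = 2.98e-09) and CMC125C by 9.12 ± 0.84. CMG220C (-2.13 ± 0.25) and CMS434C (-1.98 ± 0.20) were the largest falls among eligible genes. Of 2415 genes called, 1253 were higher and 1162 lower, and 682 changed at least 2-fold, 532 higher and 150 lower. Of the plastid genes, 133 were higher and 4 lower with a median of 1.92, CMV077C by 7.01 and CMV071C by 5.64. In EZ NL, CMV077C was near the floor at 0.345 ± 0.426 CPM, and CMV071C stood at 13.8 ± 5.41 CPM. The set was called with the preset correlation (adjusted p = 1.10e-14) and not with an estimated one (adjusted p = 0.518). The mitochondrial and chromosome-end sets were not called (adjusted p = 0.451 for both). The 10 most abundant genes held 27.2 ± 9.47% of counts in EZ P and 6.75 ± 0.691% in EZ NL. In EZ T against NL, 795 genes were called, 379 higher and 416 lower, of which 42 changed at least 2-fold (30 higher, 12 lower). CMJ101C rose by 8.59 ± 0.89 to 0.884 ± 0.162% of counts and CMC125C by 3.93 ± 0.66, while CMV141C stood at -1.55 ± 0.46 and CMP178C at -1.16 ± 0.20. Of the plastid genes 12 were higher and 3 lower, with a median of 0.074, and neither this set (adjusted p = 0.254) nor the mitochondrial (adjusted p = 0.333) or chromosome-end set (adjusted p = 0.728) was called. With an estimated correlation over all libraries the plastid set had an adjusted p of 0.779. Without EZ NL replicate 3 it was called higher at the preset correlation (0.25, adjusted p = 0.00890), and its median was below 0 without EZ NL replicate 2 (-0.10) or EZ T replicate 3 (-0.062). The count in EZ T was 489 without EZ NL replicate 1, 497 without EZ NL replicate 3 and 1378 with the P libraries left out.

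In EZ PL against NL, edgeR and DESeq2 each called 0 genes, with 116 at an unadjusted p under 0.05 in edgeR. The fit with the replicate number as a block called 1 lower gene. The numbers were not taken to pair the libraries of this comparison, since r within pairs ranged from -0.034 to 0.309. Pairing is not excluded by that. CMJ101C was at 0.34 ± 0.65 (adjusted p = 0.999), and CMT010C was at 52.0 ± 14.8 CPM in NL and 56.2 ± 2.76 in PL. The plastid set had a median of -0.20 and was called lower with the preset correlation (adjusted p = 0.00219) but not with an estimated one (adjusted p = 0.583). That call was also lost without EZ NL replicate 3 (median -0.016, adjusted p = 0.836) or EZ PL replicate 3 (-0.12, adjusted p = 0.346). The mitochondrial and chromosome-end sets were not called (adjusted p = 0.525 and 0.0817), but the latter was called higher without EZ NL replicate 2 (median 0.038, adjusted p = 0.0292 at the preset correlation, and 0.110 over all libraries with an estimated one).

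In EZ PLT against T, 39 genes were called, 38 higher and 1 lower. CMJ102C rose the most among eligible genes, from 85 ± 29 to 1271 ± 600.9 CPM (3.90 ± 0.45, adjusted p = 3.50e-05). Its neighbours CMJ103C (2.72 ± 0.43, adjusted p = 0.00378) and CMJ099C (2.11 ± 0.46, adjusted p = 0.0297) were also higher, as was CMI250C (1.44 ± 0.26, adjusted p = 0.0150). The other 34 higher genes were plastid genes, among them CMV012C (3.72 ± 0.73, adjusted p = 0.0195), CMV011C (3.63 ± 0.67) and CMV010C (3.51 ± 0.64). The plastid median was 1.45, with 99 genes higher and 1 lower adjusted over the list alone, and the set was called with the preset correlation (adjusted p = 4.49e-88) and an estimated one (adjusted p = 0.00946). CMJ308C was the lower gene (-1.50 ± 0.33, adjusted p = 0.0297), and CMJ101C was not called (1.26 ± 0.64, adjusted p = 1). With organelle genes left out, 3 genes were called higher and 0 lower. The mitochondrial and chromosome-end sets were not called (adjusted p = 0.316 and 0.938). The count was 1 without EZ T replicate 1 or 3, 3 without EZ PLT replicate 3, 6 without EZ T replicate 2 or EZ PLT replicate 1, and 80 without WT P replicate 2. It was 20 without the PL libraries numbered 2, 24 at a mean log2 CPM of at least 3, 101 with the P libraries left out, 91 in a fit on only the T and PLT libraries and 74 by DESeq2.

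Differences of the mutant without heat were measured by comparing EZ with WT in NL. All EZ libraries are of the single mutant Cme(z)-1, so loss of E(z) cannot be told apart from other differences between the strains. Of 65 genes called, 43 were higher and 22 lower, and 45 differed at least 2-fold (34 higher, 11 lower). CMT003C was higher by 5.88 ± 0.44 on the log2 scale, from 1.60 ± 0.902 to 92.5 ± 55.6 CPM (SD, n = 3 each). CMP358C was higher by 5.17 ± 0.35 (12.2 ± 3.15 to 435.3 ± 97.2 CPM), CMD191C by 4.52 ± 0.28, CMC188C by 2.97 ± 0.19 and CMA142C by 2.69 ± 0.20. CMT003C and CMP358C, the largest rises among eligible genes, lie at the outermost position of a chromosome end. CMD191C, CMC188C and CMA142C were taken by the rule as members of the chromosome-end set, so their position is no result. CMM069C (-3.23 ± 0.20, from 254.5 ± 39.3 to 27.1 ± 3.68 CPM) and CMO185C (-2.74 ± 0.22) were the largest falls among eligible genes. Of the 191 end genes tested, 16 were higher (8.38%) and 1 was lower, against 27 of 4687 other genes higher (0.576%; Fisher's exact test, two-sided, p = 1.71e-12). Adjusted over the list alone, 30 were higher and 5 lower. Camera called the set with the preset correlation (adjusted p = 1.46e-13) and with an estimated one (adjusted p = 7.88e-08), at a median of 0.12. By position, 12 of 37 outermost genes were higher (32.4%), 2 of 37 at the second position and 23 of 4282 beyond the tenth (0.537%). The plastid and mitochondrial sets were not called (adjusted p = 0.676 and 0.723). The plastid set, at a median of 0.072 (adjusted p = 0.902 with an estimated correlation), was called higher at the preset correlation without WT NL replicate 3 (0.29, adjusted p = 0.0149) or EZ NL replicate 2 (0.22, adjusted p = 0.00964), and its median was below 0 without WT NL replicate 1 (-0.055) or EZ NL replicate 3 (-0.16). CMJ101C differed by 0.0053 ± 0.66 on the log2 scale (adjusted p = 1). The count was 31 with the genotypes of the PL libraries numbered 2 exchanged, 105 with the P libraries left out and 101 by DESeq2.

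**Figure D4:**
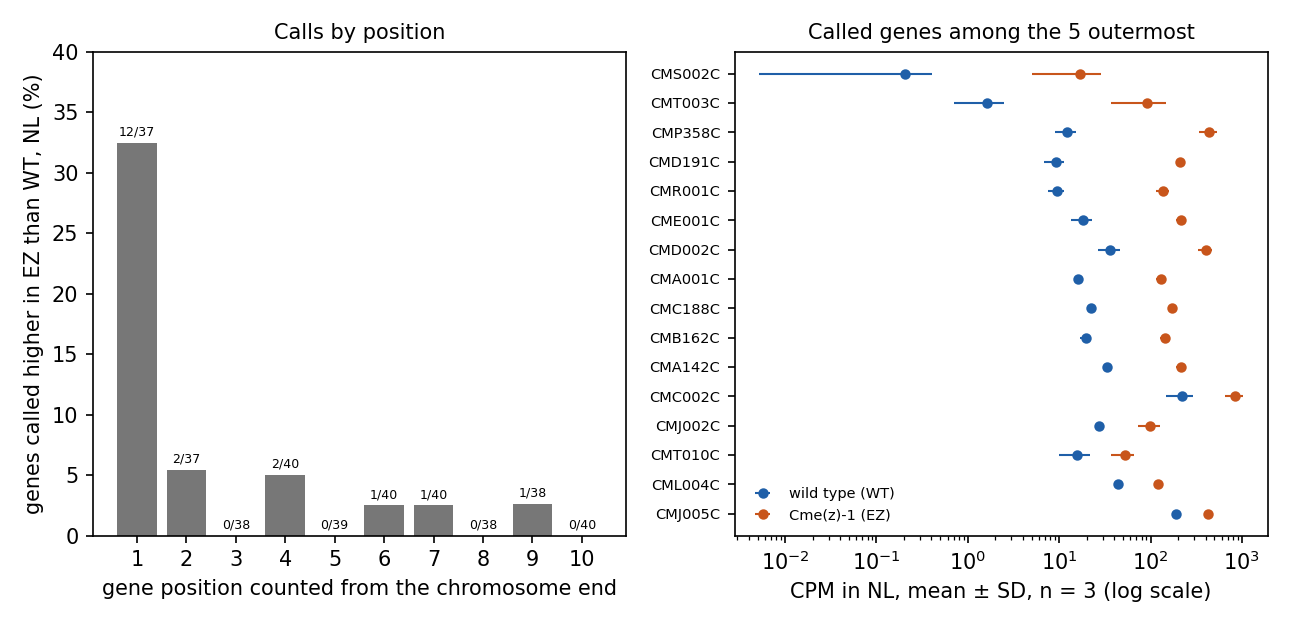
Left, share of tested genes called higher in EZ than in WT (NL) at each of the 10 outermost positions, with called and tested genes above each bar. Right, CPM on a log axis (mean ± SD, 3 libraries) in EZ (orange) and WT (blue) of the 16 genes called higher among the 5 outermost positions. The 1 gene called lower there is not drawn.

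The responses of the genotypes were compared directly. edgeR called 0 genes for the EZ minus WT difference of P against NL, T against NL, PL against NL and PLT against T, with 226, 8, 72 and 13 genes at an unadjusted p under 0.05. DESeq2 called 1 gene for P and 0 for the others. For P, 46 genes were called (29 higher, 17 lower) without WT P replicate 2. The difference for CMJ101C was -0.77 ± 0.91 in P, 0.84 ± 0.91 in T, -0.10 ± 0.92 in PL and -0.63 ± 0.90 in PLT against T. The plastid set was lower in EZ for P (median -0.57, adjusted p = 3.06e-06) and T (-0.23, adjusted p = 0.0148) with the preset correlation, and for neither with an estimated one (adjusted p = 0.669 and 0.953). It was not called for PL (median -0.12, adjusted p = 0.590, and 0.896 with an estimated correlation) or PLT against T (-0.11, adjusted p = 0.0903 and 0.724). These differences rested on single libraries, and the values that follow are at the preset correlation. For P the call was lost without WT P replicate 3 (-0.050, adjusted p = 0.629) or replicate 1 (-0.45, adjusted p = 0.0968), and the median was -1.07 without WT P replicate 2, -0.92 without EZ P replicate 3, -0.88 without WT NL replicate 3 and -0.30 without EZ NL replicate 3. For T it was lost without WT NL replicate 1 (-0.11, adjusted p = 0.972) or 2 (-0.19, 0.177), EZ NL replicate 1 (-0.21, 0.0852) or EZ T replicate 1 (-0.19, 0.510) or 2 (-0.14, 0.115). The T median was above 0 without WT T replicate 1 (0.080, adjusted p = 0.0518) or EZ NL replicate 3 (0.014, 0.928), -0.45 without WT NL replicate 3 and -0.38 without WT T replicate 3 or EZ NL replicate 2. For PL the set was called lower without WT NL replicate 3 (-0.27, adjusted p = 0.00163), WT PL replicate 1 (-0.27, 0.000348) or EZ NL replicate 2 (-0.26, 0.000438), and its median was above 0 without WT NL replicate 1 (0.021), WT PL replicate 2 (0.016) or EZ NL replicate 3 (0.095). For PLT against T it was called higher without WT PLT replicate 1 (0.33, adjusted p = 2.34e-07). It was called lower without WT T replicate 1 (-0.43, adjusted p = 3.78e-11), WT PLT replicate 2 (-0.21, 6.17e-06) or 3 (-0.23, 5.48e-06), EZ T replicate 1 (-0.13, 0.00350) or EZ PLT replicate 1 (-0.15, 0.0212) or 3 (-0.15, 0.000824). The median was above 0 and not called without WT T replicate 2 (0.026) or 3 (0.031), EZ T replicate 3 (0.033) or EZ PLT replicate 2 (0.016). Across the 4878 genes, which are not independent replicates, the WT and EZ log2 fold changes had Pearson r = 0.950 (Spearman rho = 0.914) for P, 0.876 (0.886) for T, 0.240 (0.301) for PL and 0.872 (0.559) for PLT against T. Of the genes called in P, 1062 were higher and 970 lower in both genotypes, where independent lists would share 340.1 and 308.2. For T these were 340 and 340, against 43.4 and 43.0, and for PLT against T 18 and 0, against 0.179 and 0.00041. Most higher genes in both PLT lists were plastid genes, which moved together, so independent lists are a poor guide there. The lists compared share no library, and 0 genes were called in opposite directions.

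The effect of earlier heat under 60 °C was set against its effect without it, as the PLT minus T difference minus the PL minus NL difference. CMJ102C was the gene called in each genotype, at 3.37 ± 0.59 in WT (adjusted p = 0.0313) and 3.77 ± 0.59 in EZ (adjusted p = 0.00628), with 107 genes at an unadjusted p under 0.05 in each. The plastid set was higher, with medians of 1.61 in WT (adjusted p = 4.54e-84, and 0.0113 with an estimated correlation) and 1.57 in EZ (4.63e-87 and 0.00985). The WT count was 0 without any 1 of the WT NL or WT PL libraries, WT T replicate 2 or 3, or WT PLT replicate 1 or 2, and 5 without WT P replicate 2. The EZ count was 5 without WT P replicate 2, 2 without EZ T replicate 2 or EZ PLT replicate 3, and 39 in a fit on only the groups compared, while both counts were 0 without the PL libraries numbered 2 and 9 and 10 without the P libraries.

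The last question was which genes of the 57 °C response were seen again. None of the genes called in P against NL was called in PL against NL, where 0 were called. The log2 fold changes of P and PL against NL, which share the NL libraries, had r = 0.0171 across genes in WT and 0.0325 in EZ. Unchanged groups simulated against the same controls gave means of 0.481 and 0.484. The covariances were 0.00403 and 0.00591, against 0.0348 and 0.0349 in the simulations. The simulated counts took each gene's spread from all 30 libraries, the scattered P libraries included, and used another offset before the logarithm. The simulations are therefore no measure of what the shared NL libraries give in these data, and nothing was concluded from them. All 23 genes higher in WT PLT against T and all 38 in EZ were also called higher in P against NL of the same genotype, where independent lists would share 6.24 and 9.76. Of these, 21 in WT and 34 in EZ were plastid genes. The plastid set had 160 of 196 genes in WT and 133 in EZ called higher in P. Much of the overlap is therefore that set moving together, which independent lists do not allow for. None of the 2 and 1 lower genes was called lower in P. PLT, T, P and NL share no library in these lists. P and T, both set against NL, shared 319 higher and 365 lower genes in WT and 248 and 338 in EZ. The shared NL libraries can raise these counts by an amount that was not measured.

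Genes of the 57 °C response were also summarised per library as response scores, over nuclear genes other than CMJ101C that changed at least 2-fold in P of the other genotype. For the higher list, the score was 6.95 ± 0.0062 in WT T and 7.06 ± 0.017 in WT PLT (mean log2 CPM, SD, n = 3), and 6.98 ± 0.048 and 7.11 ± 0.061 in EZ. The PLT minus T difference was 0.10 in WT and 0.13 in EZ (exact two-sided permutation p = 0.005, the smallest that 400 arrangements can give, adjusted p = 0.02). The score rose in all 6 pairs of same-numbered libraries, and with labels exchanged only within pairs the exact p was 0.03125, the smallest that 64 arrangements can give (adjusted p = 0.03125 over the 2 paired tests). Adjusted together with the PL tests it could not fall below 0.0625. Camera gave the list in PLT against T a median of 0.071 in WT (adjusted p = 0.114) and 0.057 in EZ (adjusted p = 0.0271), and called it in neither with an estimated correlation (adjusted p = 0.925 in both). The PL minus NL difference of this list averaged -0.020 over both genotypes (exact p = 0.545, adjusted p = 0.727). For the lower list the differences averaged -0.039 for PLT minus T (exact p = 0.075, adjusted p = 0.15) and -0.0021 for PL minus NL (exact p = 0.925, adjusted p = 0.925). The lower-list score fell from T to PLT in all 6 pairs, which gives the same smallest p within pairs. Camera gave this list in PLT against T a median of -0.033 in WT (adjusted p = 0.226) and -0.051 in EZ (adjusted p = 0.00434), and called it in neither with an estimated correlation (adjusted p = 0.925 and 0.816).

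**Figure D5:**
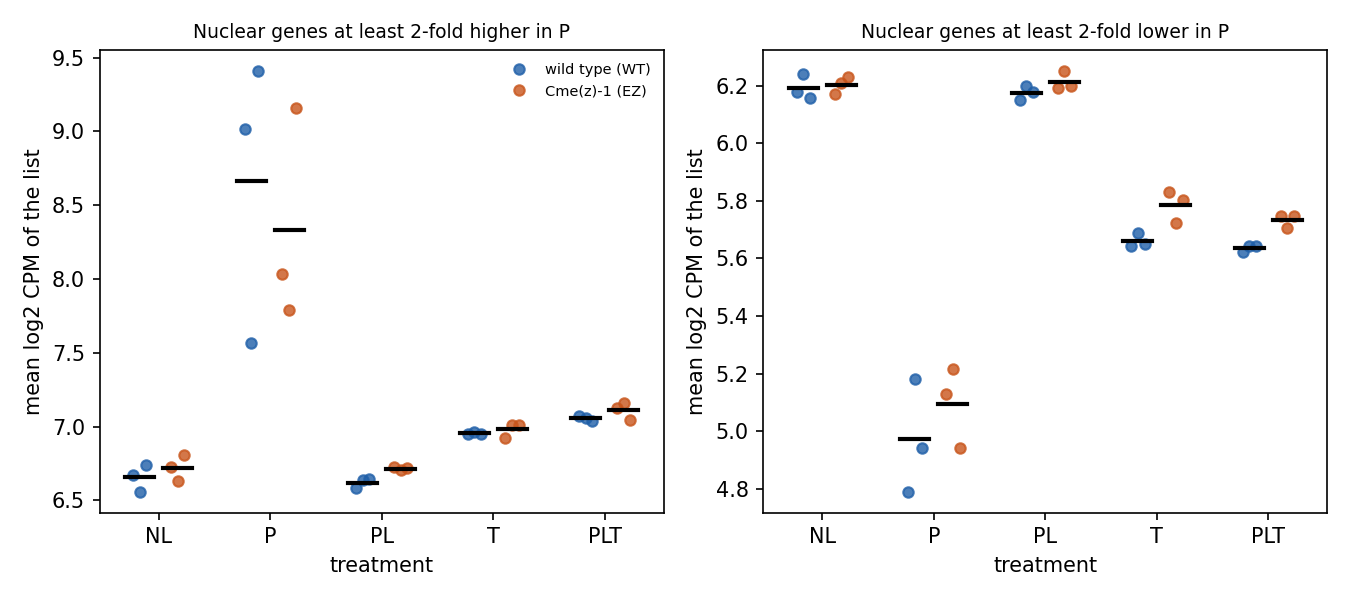
Mean log2 CPM per library of nuclear genes at least 2-fold higher (left) or lower (right) in P of the other genotype, by state, with bars at the mean of 3 libraries. In the higher list every PLT library lies above every T library of its genotype. Each genotype has its own lists, so levels are not comparable between genotypes.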

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

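The tests of a fixed and a varying share of reads from CMJ101C, of reads shared with CMJ103C and of the most abundant genes, and those of a uniform carry-over and of the scaling for plastid genes, were chosen after the result was seen; the test of an even background over the plastid genome was not.

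CMJ102C stood out because the earlier 57 °C treatment was followed by a different change under 60 °C (PLT minus T) than without it (PL minus NL), by 3.37 ± 0.59 on the log2 scale in WT (SE, adjusted p = 0.0313) and 3.77 ± 0.59 in EZ (adjusted p = 0.00628). A fixed share of reads running on from CMJ101C is argued against, since the extra CMJ102C counts per extra CMJ101C count were at least 10.4 times as high in PLT as in T in both genotypes, and unequal scaling from a few abundant genes is too small, with factors of T and PLT differing by at most 0.0682 on the log2 scale against a change of 3.22 or more. A share that varies with the heat state stays open, because that quotient was 2.42% to 4.01% in the WT PLT libraries, within the 0.821% to 5.08% of WT P, and 4.43% to 8.28% in EZ PLT, mostly above the 0.744% to 4.65% of EZ P, and on average 1.37 (WT) and 2.10 (EZ) times as high in PLT as in P. Reads shared with the neighbour CMJ103C remain open as well, since the extra CMJ102C counts per extra CMJ103C count in PLT averaged 1.80 (WT) and 1.40 (EZ) times those in P and the EZ libraries overlapped, although every WT PLT library (193% to 414%) lay above every WT P library (142% to 176%) and CMJ103C in WT PLT against T was not called (1.17, adjusted p = 0.305). CMJ099C, also of this locus, was at 1.96 ± 0.46 in WT PLT against T (edgeR adjusted p = 0.0507) and 2.11 ± 0.46 in EZ (0.0297). In the contrast of differences it was at 2.44 and 3.03 and was not called (adjusted p = 0.593 and 0.206). The biological reading, that the locus responds more to 60 °C after earlier heat, is therefore a hypothesis. It may concern CMJ102C together with CMJ103C and CMJ099C. The WT count of 1 was 0 without any 1 of 10 libraries of the NL, PL, T and PLT groups.

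The plastid genes stood out in the same contrast, with medians of 1.61 in WT and 1.57 in EZ on the log2 scale (adjusted p = 4.54e-84 and 4.63e-87, and 0.0113 and 0.00985 with an estimated correlation). The scaling of the libraries is argued against, as the median PLT to T ratio on raw totals was at least 1.37 in both genotypes on the log2 scale. A carry-over of RNA without poly(A) tails that raises every plastid gene by the same factor is argued against. The other plastid genes rose more than the 20 most abundant ones in each of the 6 pairs of PLT and T libraries. Their lead was 0.976 to 2.14 on the log2 scale, against at most 0.897, either way, between replicates. Carry-over that raises genes by unequal factors, such as one added to counts present without it, was not tested and stays open. An even background over the plastid genome, such as carried-over DNA, cannot be told apart from a change in plastid RNA, because the profile of gained counts differed between P and PLT by 1.17 to 1.62 times the difference between genotypes, which decides neither way. The 20 most abundant plastid genes had medians of 0.23 in WT and -0.052 in EZ for PLT against T, while the other plastid genes had 1.70 and 1.64. An even background, an unequal carry-over or a change in plastid RNA could give that split.

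The plastid set also differed between genotypes in its change from NL to P, with a median EZ minus WT difference of -0.57 (adjusted p = 3.06e-06, and 0.669 with an estimated correlation). It ranged from -0.050 (adjusted p = 0.629) without WT P replicate 3 to -1.07 without WT P replicate 2, and the call was also lost without WT P replicate 1 (-0.45, adjusted p = 0.0968). The median was -0.92 without EZ P replicate 3, -0.88 without WT NL replicate 3 and -0.30 without EZ NL replicate 3. For T against NL the median difference was -0.23 (adjusted p = 0.0148, and 0.953 with an estimated correlation). It was above 0 without WT T replicate 1 (0.080, adjusted p = 0.0518) or EZ NL replicate 3 (0.014, adjusted p = 0.928), -0.45 without WT NL replicate 3 and -0.38 without WT T replicate 3 or EZ NL replicate 2. The call was lost as well without WT NL replicate 1 or 2 (-0.11 and -0.19, adjusted p = 0.972 and 0.177), EZ NL replicate 1 (-0.21, adjusted p = 0.0852) or EZ T replicate 1 or 2 (-0.19 and -0.14, adjusted p = 0.510 and 0.115). Groups of 3 libraries were not tested for single outlying libraries, and WT P replicate 2 stood apart from its group, at 12.6 on the first principal component against 61.6 and 72.0.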

How the results depend on the processing

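The fit without the P libraries, the plastid set of differences between effects, WT P replicate 2 left out of comparisons that do not use it, the genotype average and the exchange within pairs were chosen after the data were seen. RLE scaling and no filter changed no count by more than 1.5 times. The cause was not tested where none is named. At an absolute log2 fold change of at least 1, a stricter rule by construction, WT P gave 815, WT T 73, EZ P 682 and EZ T 42 genes, and the share of higher genes in WT P was 78.0% against 50.6%. With organelle genes left out, WT PLT against T gave 1 gene and EZ PLT against T 3, where 21 of 25 and 34 of 39 calls had been plastid genes. At a mean log2 CPM of at least 3, EZ PLT against T gave 24. DESeq2 gave 3 for WT PL, 82 for WT PLT against T, 74 for EZ PLT against T, 101 for EZ against WT in NL, 1 for the difference of P, and 8 (WT) and 5 (EZ) for PLT minus T against PL minus NL. Fits on only the groups compared gave 1462 for WT P, 0 for WT PLT against T, 91 for EZ PLT against T and 39 for EZ PLT minus T against PL minus NL. Without the P libraries the counts were 1634 (WT T), 115 (WT PLT against T), 1378 (EZ T), 101 (EZ PLT against T), 105 (EZ against WT in NL), and 9 and 10 for PLT minus T against PL minus NL. Averaged over the 5 states, EZ against WT gave 738 genes. Exchanging the genotypes of the PL libraries numbered 2 gave 31 for EZ against WT in NL. Leaving both out gave 20 for EZ PLT against T and 0 and 0 for PLT minus T against PL minus NL. With an estimated correlation the plastid set lost its call in WT P (median 2.70, adjusted p = 0.518) and WT T (0.28, adjusted p = 0.707).

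With the replicate number as a block, the count for WT PLT against T rose to 52, EZ PL against NL gave 1 and EZ PLT minus T against PL minus NL gave 2. The block moved no other count by more than 1.5 times, with 51 for EZ PLT against T and 94 for EZ against WT in NL. Among the 3 replicate numbers, 25 of 30 libraries correlated best, on average over the libraries of other groups, with those of their own number. This is a hint from the data and not from the design.

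With 1 library left out at a time, counts ranged from 608 to 1266 for WT T, 0 to 2 for WT PL, 1 to 88 for WT PLT against T, 489 to 1003 for EZ T, 1 to 80 for EZ PLT against T, 0 to 46 for the difference of P, 0 to 5 for WT and 1 to 5 for EZ PLT minus T against PL minus NL. The plastid median of WT T ranged from -0.039 (reversed, without WT T replicate 1) to 0.52, and that of the EZ minus WT difference of T from -0.45 to 0.080 (reversed without WT T replicate 1, and at 0.014 without EZ NL replicate 3). The highest counts for both PLT comparisons, for the difference of P and for both PLT minus T contrasts came without WT P replicate 2. Counts stayed within 1.5 times for WT P (2255 to 2922), EZ P (2007 to 2600) and EZ against WT in NL (47 to 80). Of all results under all alternatives, 293 main values were kept and 70 were not (65 counts moved, 4 calls were lost, 1 reversed). A count was kept if it stayed within 1.5 times or stayed at 0. A gene set was kept if its call stayed the same, whatever its size, and a change of sign counted only where the main result was called. Among the other results 244 were kept, 19 gained and 13 lost a call, 1 moved and 2 reversed. At a depth of 6276214 to 15336903 counts and 3 libraries per group, 46% of genes simulated with a 1.5-fold change in WT PL against NL were recovered. Comparisons with more changed genes called smaller changes too. In WT T against NL, 1062 genes were called and 73 of them changed at least 2-fold.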

Other observations

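The tests of E(z)-dependent genes at 57 °C, of neighbouring genes, of extra copies at chromosome ends and of other splits were set before their results were seen, and the test of shared copies, the genotype average and the account of CMT010C were chosen afterwards. Averaged over the 5 states, EZ differed from WT in 738 genes (edgeR, 353 higher and 385 lower), among them all 65 called in NL. At the outermost position of the chromosome arms 27 of 37 tested genes were higher in this average, and 63 of the end genes in all. Between NL cultures the 16 end genes called higher, CMS002C aside, were 2.26- to 59.1-fold higher in EZ. CMS002C, at an outermost position and near its floor in WT, went from 0.207 ± 0.201 to 16.7 ± 11.6 CPM (SD, n = 3), CMR001C from 9.45 ± 1.84 to 137.1 ± 21.3, CME001C from 18.2 ± 4.78 to 214.4 ± 22.2 and CMC002C from 219.0 ± 71.5 to 848.2 ± 188.4.

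CMT010C, a gene at the fourth position from a chromosome end, was low in the wild-type libraries that had been heated 24 h before. It stood at 6.58 ± 0.710 CPM in WT PL and 6.61 ± 0.306 in WT PLT, against 15.9 ± 5.96 in WT NL and 17 ± 4.1 in WT T (SD, n = 3 each). In EZ the levels were 56.2 ± 2.76 in PL and 46.3 ± 1.55 in PLT, against 52.0 ± 14.8 in NL and 53.0 ± 12.1 in T. The EZ minus WT difference was 1.38 ± 0.35 for PL against NL and 1.16 ± 0.35 for PLT against T on the log2 scale (SE), and failed the correction in both (adjusted p = 1 each).

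For the rise of genes nearest the chromosome ends in EZ, extra copies of ends that reach the inner neighbour are argued against. Of 16 inner neighbours, 1 rose by at least 0.5 of the log2 change of the called gene. That neighbour, CMJ005C next to CMJ002C, is itself among the called genes. Copies that hold the called gene without its inner neighbour could not be seen this way, and 12 of the 16 genes are at the outermost position. Sharing of reads between near-identical copies cannot be told apart from a rise of each gene. Of the 16 genes, 7 had a partner among the 43 genes called higher to which their ratio varied less over the 15 EZ libraries than to every uncalled nuclear gene at least as abundant, which decides neither way. That E(z) keeps the outermost genes low may be the reason for the rise, a hypothesis on which the histone mark at these genes in both genotypes would bear. That mark would not settle the sharing of reads or other differences between the strains, and no such data were analysed here.

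It was also asked whether genes kept low by E(z) rise in wild type at 57 °C. The 50 genes at least 2-fold higher in EZ in the PL, T and PLT libraries had a median log2 fold change of 0.45 in WT P against NL, with 13 called higher and 5 lower, and camera did not call the list (p = 0.0550, and 0.429 with an estimated correlation). In EZ P against NL the median was 0.11, and camera did not call the list either. The data did not bear the hypothesis out at the threshold set.

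Adjacent nuclear genes had correlated changes between NL and P. Over 4649 adjacent pairs, the ranked log2 fold changes in WT P against NL correlated at 0.216, above the highest of 1000 orders permuted within chromosomes (0.0454; p = 0.001, the smallest they can give). The values were 0.206 for EZ P against NL and 0.137 for EZ against WT in NL. Shared chromatin could give such a correlation, and so could reads counted for overlapping neighbours, which an unstranded library cannot separate.

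Other splits of the same libraries were fitted as a check on the counts. For the 9 comparisons of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05. WT P against NL gave 2618 genes and the highest other split 846, for which the cause was not tested. EZ against WT in NL gave 65 and the highest other split 1. WT T (1062), WT PLT against T (25), EZ P (2415), EZ T (795) and EZ PLT against T (39) had 0 in every other split. In each of these 7 the real split alone, 1 of 10, was as large, and in both PL comparisons all 10 splits gave 0, which says nothing where 0 genes were called. In the 3 comparisons whose numbers pair the libraries, the 3 other splits that part as many pairs gave 0, and the remaining splits, which keep more pairs together, gave at most 1.

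For the contrasts of differences, 100 of 200 possible splits were drawn. With 0 genes called for the EZ minus WT differences, all 100 must give at least as many, so this count says nothing about them, and the highest other splits gave 1604 (P), 64 (T), 179 (PL) and 34 (PLT against T). For PLT minus T against PL minus NL, 5 of 100 splits in WT and 14 of 100 in EZ gave at least the 1 gene called, so chance was not excluded, with 84 and 2 in the highest other split. What gave the counts of 1604, 179, 84, 64 and 34 was not tested.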
